A study of Arabidopsis thaliana with 8 samples.

How the data were processed

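RNA from Arabidopsis thaliana Col-0 seed was hybridised, after biotin labelling, to single-colour expression arrays, on which a probe set of several probes stands for a transcript. The 8 arrays fall into 4 groups of 2: dry seed, seed imbibed for 24 h in water, seed imbibed for 24 h in 3 µM abscisic acid (ABA), and seed imbibed for 24 h in 30 µM ABA. Replicates carry the letters A and B from the sample titles. Both arrays of a group share a title number, except that those in 3 µM ABA carry the numbers 3 and 5. The labels do not say whether 3 µM replicate B came from a separate experiment, so the SD of that group may include a difference between experiments. Nothing in the labels says that the arrays of a group came from separate seed batches, so p-values measure the spread between these samples, which may be technical.

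The values deposited by the authors are signal intensities on a linear scale, 1 per probe set and array. MAS5 is named in the submitters' processing notes, with no version given. The 2% trimmed mean of every array lay between 100.007 and 100.009, so the deposited scaling sets a common trimmed mean. Such scaling assumes similar total signal in all samples, and it hides any difference in total messenger RNA between dry and imbibed seed. No detection calls were used here, and low signals have no stated background limit. The number of arrays limits the precision.

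The table held 22810 probe sets, of which 64 were controls and 22746 were not. A table of platform annotation named 1 gene for 13513 probe sets, several for 503 and none for 8730, which are called unnamed here. Of the single-gene probe sets, 13436 matched the RefSeq gene table of the TAIR10.1 assembly, which served for names only. The sources used here name no genome build for the array, so no coordinates are given. Only 61 of the 309 members of the gene lists fixed before the data were examined had a named probe set. The lists of ABA synthesis, receptors and phosphatases, among others, had no named probe set that was kept, so probe sets of most known ABA response genes could only enter the fit unnamed.

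Signals were transformed as log2(signal + 3.99), the pseudocount being the 20th percentile of all deposited values. Probe sets with a mean log2 value above the 30th percentile were kept, leaving 15922, of which 8898 named a single gene. Fold changes are on the log2(signal + pseudocount) scale, which understates the change of dim probe sets. All 8 arrays entered a single fit in limma 3.58.1 under R 4.3.3, with 4 residual degrees of freedom and empirical Bayes moderation with an intensity trend. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A permutation of 2 arrays against 2 cannot go below p = 0.333, so single values per array are given without a test.

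Gene lists were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, wherever 5 or more members were kept. Of the 17 lists fixed before the data were examined, 12 had a kept member and 3 could be tested. Because of this shortfall 20 lists were added after the table of probe genes was seen and before fold changes were computed. Of these, 19 could be tested. Values of the control probe sets and of the top lines of the table, including mitochondrial nad4L, had been seen before the lists were added. Adjusted p-values were computed over the fixed lists and over the added lists separately, for each contrast. The added lists take genes that the table of probe genes names, by symbol, locus or organelle, and a wider list extends a fixed list in this way. Of the single-gene probe sets, 11933 carry a locus code as their symbol, so a list drawn by symbol can miss members of its family. Counts of members refer to the lists and not to whole families. A gene with several probe sets was represented by the brightest, and a probe set of several genes stood for a member only in these tests and in the plot of lists. Lists were tested for 4 of the 6 contrasts.

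Named genes followed a rule written before the data were examined. It takes the 5 highest and 5 lowest fold changes among called, brighter, single-gene probe sets whose arrays do not overlap, and up to 3 called members of each list. Where fewer than 2 members of a list were called, the member with the smallest p is also named. A set of ABA and germination genes was always to be named, but of these only ICL has a named probe set here. The same rule was applied to the added lists.

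The position of each array between dry seed (0) and water (1) is its projection on the line between the group means, with a dry or water array projected on a line drawn without it. Comparisons that share the water arrays were set against 100 simulations of unchanged groups. The fit was tested on simulated data for the comparison of 30 µM ABA with water, with 15922 probe sets, 200 of them changed, in 20 draws. It recovered 50.9% of changes of 1 on the log2 scale and 97.0% of changes of 2, and 6.46% of its calls were false. In the unchanged comparison of 3 µM ABA with water it made 0.35 calls per draw. The simulated noise was independent between probe sets, with its spread taken from the fit to these arrays. All groups started from the water mean. Shifts shared across an array were not simulated, so these rates may not hold for the real arrays.

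Alternatives covered the pseudocount, the scaling between arrays, the filter, the variance trend, a block by letter, the arrays in the fit, the threshold, probe sets shared between transcripts, and each array left out. Scaling to the spike-in control probe sets, fits without the dry or the 3 µM arrays, and the mean of both ABA doses against water were alternatives added after seeing the data.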

Results

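Transcript levels were measured in Arabidopsis seed before and after 24 h of imbibition, in water or in ABA, the hormone that maintains seed dormancy and restrains germination. Each of the 4 groups had 2 arrays. The median signal was 21.0 and 21.4 on the dry arrays and lay between 30.9 and 33.8 on the imbibed arrays, with a common trimmed mean. The ratio of 3' to 5' signal of the GAPDH control transcript, a sign of RNA quality, was 1.31 and 1.05 in water and 0.884 to 0.974 in ABA, and that of actin in another set of control probe sets was 2.94 and 3.80 in water and at most 2.73 in ABA. The other 4 of 6 such ratios overlapped between water and ABA, and 5 were highest in water replicate A among the imbibed arrays. In 2 of the 6 the dry arrays lay apart from all imbibed arrays, at 1.81 and 1.69 against 0.371 to 0.927 for GAPDH and at 4.34 and 4.52 against at most 3.80 for actin, both in that other set. Arrays of a group correlated at r = 0.969 to 0.983 across probe sets, and dry against imbibed arrays at 0.583 to 0.703. Probe sets are not independent replicates. Arrays of different imbibed groups correlated at 0.964 to 0.983, so that treatment groups were about as close to each other as replicates were.

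The first comparison asks which transcripts changed during 24 h in water, between groups that also differ in the 2 control ratios given for dry seed. Of all probe sets tested, 66.0% were called, 37.5% higher and 28.5% lower in water with the deposited scaling. Counts of called members in this comparison are to be read against these shares. All 7 measured cell wall loosening genes and 6 of 7 tubulins were called higher, and all 9 genes of a wider list of seed storage and oil body proteins lower, while genes of protection against drying went both ways. EXPA9, an expansin, rose from a signal of 9.25 ± 1.57 to 1328 ± 296 (SD, n = 2), and EXPA8 from 7.49 ± 1.63 to 1014 ± 4.66. TUA6, an alpha-tubulin, rose from 16.7 ± 5.37 to 1691 ± 370. AT1G03890, a cruciferin-type storage protein, fell from 1987 ± 96.4 to 28.7 ± 1.21, and the dehydrin LTI30 from 2892 ± 907 to 71.2 ± 45.9.

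All 7 measured members of the cell wall loosening list rose, both over all probe sets and adjusted over the list alone, with a median log2 change of 3.59 (camera adjusted p = 0.00014 in limma, adjusted p = 0.0853 with an estimated correlation). XTH16, a xyloglucan-modifying enzyme, changed by 5.89 ± 0.20 (SE). Of 16 cytosolic ribosomal proteins, 11 rose, also adjusted over the list alone. Their median change was 1.12 (adjusted p = 0.00333, adjusted p = 0.463 with an estimated correlation). AT2G40010 and AT3G53890, of the acidic P0 and S21 families, rose by 3.68 and 2.65 on the log2 scale. Of 9 LEA and ABA-induced protectants, 5 fell and 1 rose, with the same counts adjusted over the list alone, and the list as a whole did not pass (median -0.92, adjusted p = 0.12). Without dry replicate B it passed (median -1.75, adjusted p = 0.0178), as with spike-in scaling (median -0.019, adjusted p = 0.0494). The exception was the dehydrin COR47, which rose from 6.57 ± 0.79 to 316.9 ± 116, whereas M17 fell from 2024 ± 347 to 263 ± 149.

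The other lists fixed beforehand were too small for a set test, and their counts were the same adjusted over the list alone, which for a list with 1 kept member is no adjustment. All 4 storage and oil body members fell, the oleosins AT3G01570 and OLEO3 by -1.93 and -1.87. All 4 heat shock members fell, among them AT1G53540, a small heat shock protein, from 993 ± 379 to 23.5 (log2 change -5.30 ± 0.63 SE). In photosynthesis, PORB and RCA, for chlorophyll synthesis and Rubisco activation, rose by 3.47 and 2.64, and 2 of 4 members fell, including the antenna gene LHCB4.2 at -2.17. Of 3 genes of gibberellin metabolism and signalling, the receptor genes GID1A and GID1C fell by -2.27 and -1.92. SLY1, for the F-box protein of the pathway, changed by 0.55 with the deposited scaling and lay at -0.0059 with a common median. SPT, a bHLH regulator of germination, rose from 18.4 ± 3.36 to 245.6 (log2 change 3.49 ± 0.19 SE). PRL, a DNA replication licensing factor, rose by 3.03. Of 3 storage lipid genes, AIM1 of beta-oxidation fell by -1.48, and the lipase gene SDP1 changed by -0.73 and lay at 0.16 with spike-in scaling. ICL, for isocitrate lyase of the glyoxylate cycle, was not called (log2 change -3.44 ± 1.99 SE, limma adjusted p = 0.152). Its arrays disagreed, at signals of 3260.5 and 100.4 in dry seed and 695 and 0.127 in water. In the list of root, pollen and leaf cell markers, the guard cell lineage gene MUTE rose at a low level, from 1.47 ± 0.74 to 14.9 ± 4.09. DFR of the flavonoid pathway was not called (-0.55 ± 0.45 SE, adjusted p = 0.302).

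Lists added after the table of probe genes was seen gave further groups. All 13 mitochondrion-encoded transcripts fell (median -2.96, camera adjusted p = 1.43e-05, adjusted p = 0.342 with an estimated correlation), led by cox2, from 1225 ± 185 to 22.5 ± 4.99. In the wider LEA list 18 of 29 members fell and 6 rose (median -2.0, adjusted p = 0.0035, adjusted p = 0.499 with an estimated correlation). All 9 members of the wider storage list fell (median -2.53, adjusted p = 0.00012, adjusted p = 0.342 with an estimated correlation). Among 15 serine carboxypeptidase-like genes 11 rose (median 3.77, adjusted p = 0.00012, adjusted p = 0.189 with an estimated correlation). The highest of these, scpl44, changed by 6.94 ± 0.16 (SE), to a signal of 1348 ± 112. Of 10 autophagy genes 7 fell and 1 rose (median -1.10, adjusted p = 0.0167, adjusted p = 0.415 with an estimated correlation), with ATG8H at -4.43. Of 7 tubulins 6 rose (median 3.90, adjusted p = 0.0035, adjusted p = 0.312 with an estimated correlation).

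**Figure D1:**
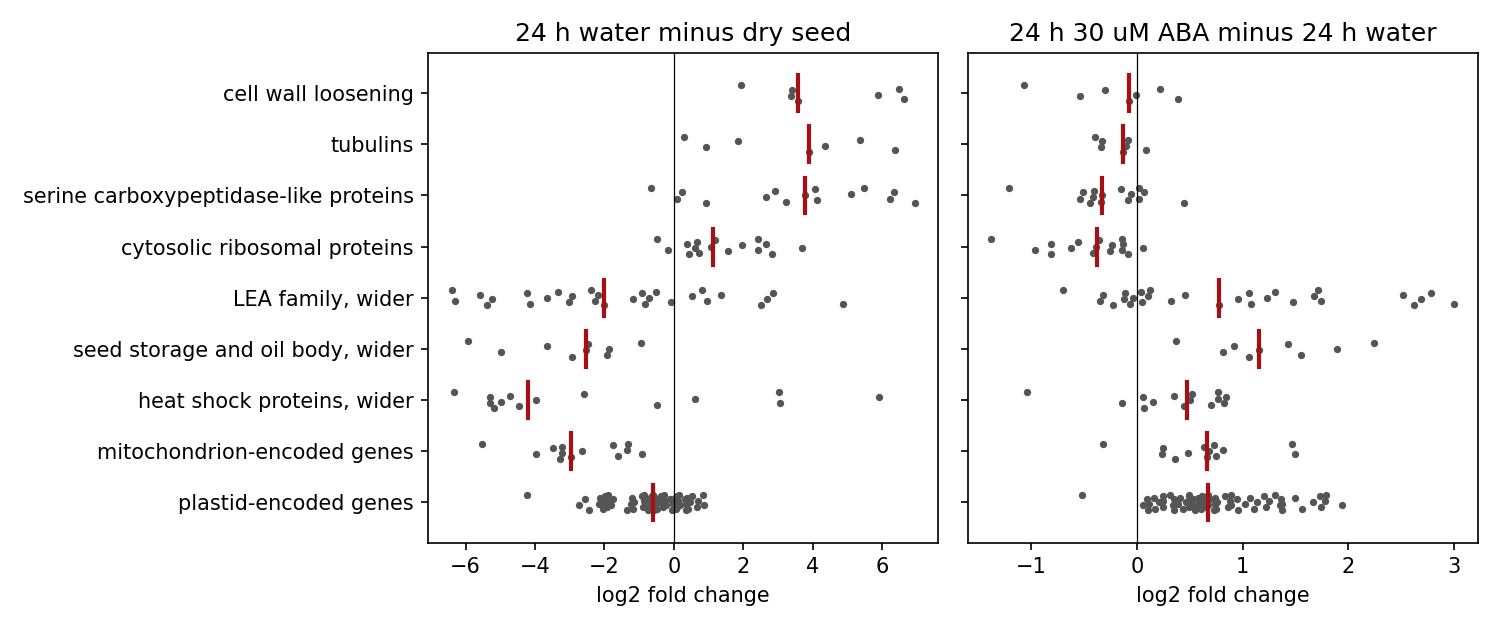
Log2 fold change of each tested list member (grey points) and the list median (red bar), for water minus dry seed on the left and 30 µM ABA minus water on the right. All 7 cell wall loosening members lie above 0 on the left, and all 9 wider storage members lie below 0 on the left and above 0 on the right.

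Among the brighter probe sets of a single gene, to which the naming rule is limited, the highest changes were of AT3G48140, from 7.24 ± 3.07 to 1551 ± 437, and of OCT1, a carnitine transporter gene, from 2.93 ± 3.65 to 879.8 ± 118. The lowest change among them was that of AT1G30860, from 1746 ± 113 to 13.3 ± 8.61. In all, limma called 10508 of 15922 probe sets, 5973 higher and 4535 lower in water. The split depended on scaling: 56.8% of calls were higher with the deposited scaling, 50.8% after quantile normalization, 37.8% with a common median and 83.2% with spike-in scaling. The median of all probe sets was 0.15, -0.03, -0.37 and 0.93 in that order. Spike-in controls, the bioB, bioC, bioD and cre probe sets, had a geometric mean signal of 339 and 363 on the dry arrays. On the imbibed arrays it was 128 to 247. Nothing in the sources used here says that these controls were added per seed or per amount of seed RNA. Spike-in scaling is therefore an alternative scaling here and not a measure of total messenger RNA.

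The next comparison asks what 30 µM ABA changed at 24 h. AT2G42560, a LEA gene, had a signal of 168 ± 29.3 in 30 µM ABA against 17.9 ± 6.83 in water and 1687 ± 340 in dry seed (log2 change 3.00 ± 0.35 SE, limma adjusted p = 0.0158). AT3G18570, of the oleosin family, had 209.8 ± 6.41 against 41.2 ± 4.25 (2.25 ± 0.19 SE, adjusted p = 0.00389). The LEA gene AT4G36600 changed by 2.78, the dehydrin AT4G39130 by 2.62, AT3G15280 by 2.91 and AT5G43770 by 2.35. AT4G36700, of the cupin storage protein family, and AT1G03890 were higher by 1.89 and 1.16.

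Limma called 72 probe sets, 66 higher and 6 lower in 30 µM ABA. Of the 66, 60 had been called lower in water than in dry seed, against 28.5% of all probe sets tested, and 54 remained called below dry seed in 30 µM ABA. These comparisons share the water arrays, so part of the opposition may come from them: across all probe sets the fold changes had r = -0.590 against -0.499 in simulations of unchanged groups, and a covariance of -0.374 against -0.0366. The water group cannot be split into separate pairs of arrays. With a different water array in each comparison the covariance was -0.345 and -0.309. All 6 that were lower, among them AT1G47400, AT5G45950, AT4G16230 and AT3G22210, had risen in water. EEL, a bZIP factor of seed maturation, and PUB19, a ubiquitin ligase, were among the higher ones, at 1.1 and 1.16, and were singled out after their values were seen. Calls were few and fragile: without water replicate A, water replicate B or 30 µM replicate B limma called 0, and without 30 µM replicate A it called 5. Spike-in scaling called 202, of which 62.4% were higher against 91.7% with the deposited scaling, and moved the median of all probe sets to -0.18.

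The GAPDH and actin control ratios that set water apart from ABA, signs of RNA quality, were higher in both water arrays than in both 30 µM arrays. In the wider storage list all 9 members were above water, 3 of them called (median 1.16, camera adjusted p = 3.46e-13, adjusted p = 0.138 with an estimated correlation, fry adjusted p = 0.0362). Adjusted over the list alone, 8 were higher. The wider LEA list had 5 of 29 called, all higher (median 0.78, camera adjusted p = 3.29e-08, adjusted p = 0.387 with an estimated correlation, fry adjusted p = 0.302). Adjusted over that list alone, 11 were higher. For the LEA and ABA-induced protectants fixed beforehand, 0 of 9 were called by limma, also adjusted over the list alone, and 3 had an unadjusted p under 0.05. Their median was 0.33 (adjusted p = 0.0387, adjusted p = 0.309 with an estimated correlation, and with the preset correlation adjusted p = 0.398 without water replicate A and 0.177 without 30 µM replicate B). M17 had 603 ± 45.4 against 263 ± 149 (adjusted p = 0.344). Of the 4 storage members fixed beforehand 1 was called and 3 passed adjusted over the list alone. PORB and RCA, at -1.36 and -0.95, were lower only when adjusted over the list alone. SPT, the only kept member of its list, lay at -0.58 relative to water (adjusted p = 0.35 over all probe sets). Of 16 cytosolic ribosomal proteins 15 lay below water with 0 called by limma, also adjusted over the list alone, and 5 at an unadjusted p under 0.05 (median -0.37, adjusted p = 1.02e-06, adjusted p = 0.309 with an estimated correlation). AT5G20290, of the S8 family, had 426 ± 105 against 1212 ± 728 (adjusted p = 0.27). Without water replicate A the ribosomal list did not pass (adjusted p = 0.122). Cell wall loosening genes did not pass (median -0.076, adjusted p = 0.117).

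Plastid-encoded transcripts were higher in 30 µM ABA than in water in 67 of 68 cases, 10 of them called (median 0.67, camera adjusted p = 8.54e-35, adjusted p = 0.0729 with an estimated correlation, fry adjusted p = 0.018). Adjusted over the list alone, 40 were higher and 1 lower. With spike-in scaling the list median was 0.47, less than the 0.55 between the water arrays, and the median of all probe sets was -0.18. That gap includes a shift of all probe sets, as the spike-in signal differed between the water arrays (168 and 209). The control ratios named above also differed between these groups. rpoC2, for a plastid RNA polymerase subunit, had 140.5 ± 17.9 against 33.8 ± 7.26, and rps4, for a ribosomal protein, 385 ± 93.2 against 109.7 ± 30.8. Mitochondrion-encoded transcripts moved alike, with 12 of 13 above water and ccb382 called at 1.46 (median 0.67, adjusted p = 2.19e-07, adjusted p = 0.271 with an estimated correlation). Signal of the 25S ribosomal RNA control probe set was 7.25 and 10.1 in water, 28.3 and 13.6 in 30 µM ABA, and 1.83 and 38.7 in 3 µM ABA.

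The arrays in 3 µM ABA carry different title numbers, 3 and 5, and the labels do not say whether they came from 1 experiment. For 3 µM ABA against water limma called 0 probe sets, with 635 at an unadjusted p under 0.05, where 796 would be so by chance. AT3G18570 had 85.2 ± 19.2, between its levels in water and in 30 µM ABA (adjusted p = 0.999). The plastid gene psbT, for a small photosystem subunit, had 30.6 ± 0.312 against 7.62 ± 0.795 in water and 34.9 ± 2.87 in 30 µM ABA (adjusted p = 0.56). Of the 66 probe sets called higher in 30 µM, 65 lay above water in 3 µM and all 66 below their level in 30 µM. They were chosen for a high level in 30 µM and a low level on the same water arrays, so both counts follow partly from the choice. Across all probe sets, without such a choice, 72.4% had the same sign at both doses, against 66.7% in simulations of unchanged groups. The plastid-encoded list had a median of 0.51 with 65 of 68 members above water (adjusted p = 1.87e-27, adjusted p = 0.113 with an estimated correlation). All 9 members of the wider storage list lay above water (median 0.53, adjusted p = 3.93e-07, adjusted p = 0.215 with an estimated correlation), as did 12 of 13 mitochondrion-encoded transcripts (median 0.50, adjusted p = 2.67e-07, adjusted p = 0.215 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.28 and 15 of 16 below water, with 0 called by limma, also adjusted over the list alone, and 4 at an unadjusted p under 0.05 (adjusted p = 7.44e-08, adjusted p = 0.258 with an estimated correlation, and adjusted p = 0.322 with the preset correlation without water replicate A). Fold changes of both doses against water had a covariance of 0.0729 across probe sets, against 0.0367 in simulations of unchanged groups with the same shared controls. With a different water array in each comparison the covariance was 0.0206 and 0.0328. Their correlation was 0.680 against 0.500 in those simulations, so part of the likeness may come from the shared controls. With spike-in scaling limma called 28 probe sets, all higher in 3 µM ABA, and the median of all probe sets was 0.28.

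**Figure D2:**
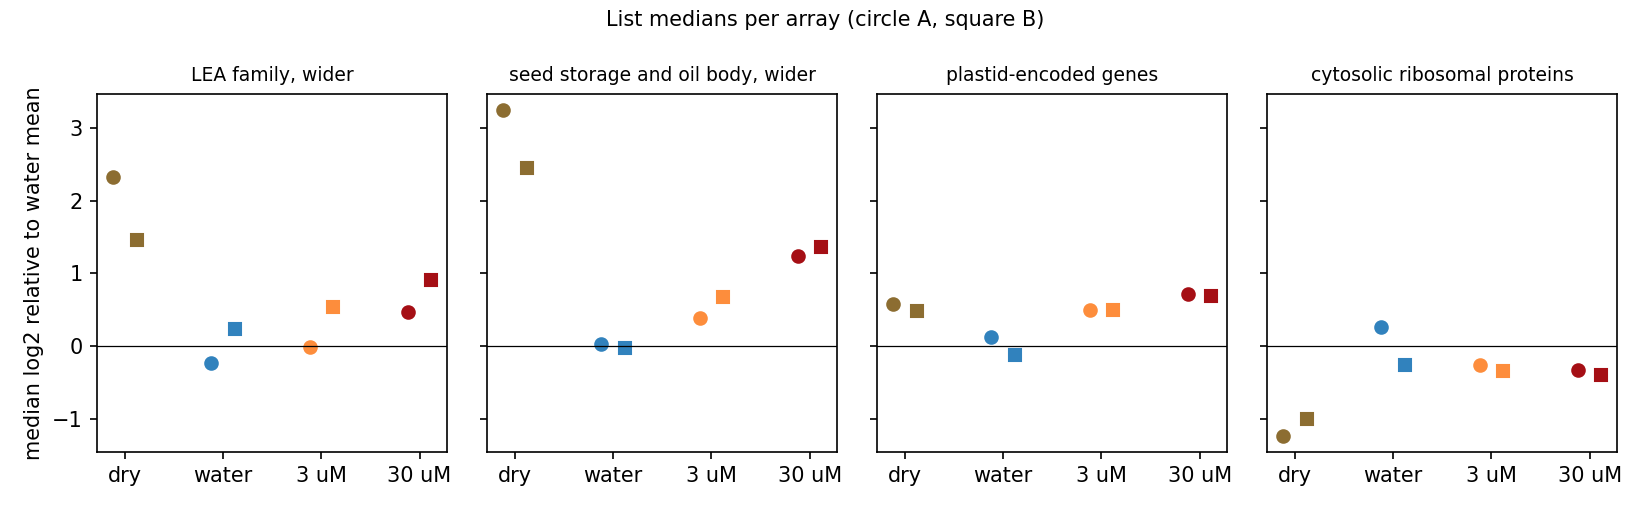
Median log2 level of 4 gene lists on each array relative to the mean of the water arrays, with circles for replicate A and squares for B. The wider storage list stands at 1.24 and 1.37 on the 30 µM arrays and at 0.38 and 0.68 on the 3 µM arrays.

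The 30 µM and 3 µM groups were also compared directly, and limma called 0 probe sets, with 513 at an unadjusted p under 0.05. The wider storage list was higher in 30 µM (median 0.70, adjusted p = 1.83e-09, adjusted p = 0.377 with an estimated correlation), and so was the wider LEA list with the deposited scaling (median 0.46, adjusted p = 4.92e-11, adjusted p = 0.377 with an estimated correlation), although its median was -0.015 with spike-in scaling, where the median of all probe sets was -0.47. Spike-in scaling called 10 probe sets. Of the probe sets changed by imbibition in water, 65.7% had the opposite sign in this contrast, which shares no array with it. Without 3 µM replicate A the share was 54.7%.

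Against dry seed, limma called 9995 probe sets in 30 µM ABA and 10287 in 3 µM ABA, with 58.5% and 58.7% higher with the deposited scaling. With a common median 34.8% and 36.6% were higher, and with spike-in scaling 82.3% and 89.5%. On the line from dry seed (0) to water (1), the 30 µM group lay at 0.877 ± 0.012 (SD, n = 2) and the 3 µM group at 0.932 ± 0.051, with water at 0.970 ± 0.017. With spike-in scaling the 3 µM group lay at 1.02, beyond the water mean, and the arrays overlapped, with 30 µM at 0.915 and 0.801 and water at 1.06 and 0.890. With the deposited scaling the 3 µM arrays lay apart, replicate A at 0.968 and replicate B at 0.896.

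**Figure D3:**
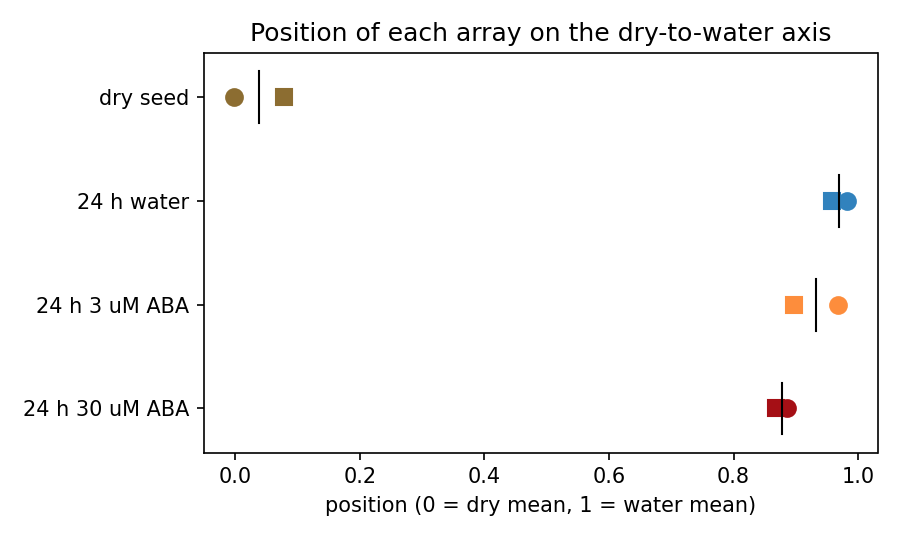
Position of each array on the dry-to-water axis, without units, where 0 is the mean of dry seed and 1 the mean of seed in water, with circles for replicate A, squares for B and black bars for group means. The 30 µM arrays lie at 0.886 and 0.869, below both water arrays at 0.982 and 0.957, all with the deposited scaling.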

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

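The tests of letters, title numbers, scaling, carry-over of RNA and slower passage in this part, and spike-in scaling, were chosen after the results were seen, whereas both tests of exchanged samples were written before, with further requirements added after. The lists below differed between 30 µM and 3 µM ABA in camera's test of that difference at the preset correlation, while none of them did with an estimated correlation (adjusted p = 0.377 for the added lists and 0.798 for the fixed list). The median log2 difference, 30 µM minus 3 µM, was 0.46 for the wider LEA list, 0.70 for the wider storage list, 0.18 for plastid-encoded genes, 0.38 for the LEA and ABA-induced protectants, -0.49 for SWEET sugar transporters and 0.0605 for UDP-glycosyltransferases. With spike-in scaling, which put the median of all probe sets at -0.47, the medians were -0.015, 0.29, -0.27, -0.098, -0.80 and -0.37 in that order, each on the same side of the median of all probe sets as with the deposited scaling (-0.018). The SWEET list did not pass without 3 µM replicate B (median 0.013, adjusted p = 0.503) or 30 µM replicate B (0.117), and the UDP-glycosyltransferases did not without 3 µM replicate A (0.0896) or 30 µM replicate B (0.12). The LEA and ABA-induced protectants did not without 3 µM replicate A (median 0.018, adjusted p = 0.752) or 30 µM replicate B (0.455). Lists that passed only with an array left out were the wider heat shock list (0.88, adjusted p = 5.24e-06), core histones (0.47, 0.00126) and mitochondrion-encoded genes (0.44, 0.0023) without 3 µM replicate B, mitochondrion-encoded genes (0.29, 0.00269) and nuclear photosynthesis genes (-0.11, 0.0231) without 30 µM replicate B, nuclear photosynthesis genes (-0.39, 0.0235) without 3 µM replicate A, and auxin genes (-0.38, 0.0451) without 30 µM replicate A. The 25S ribosomal RNA control probe set, used in no comparison, exceeded its level in water and dry seed on 3 arrays, at 28.3 and 13.6 in 30 µM ABA and 38.7 in 3 µM replicate B.

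With the deposited scaling the arrays in 3 µM ABA lay apart between dry seed and water, at 0.968 and 0.896 (1.12 and 0.927 with spike-in scaling), and their titles carry the numbers 3 and 5, where the arrays of every other group share a number. A 30 µM sample under the name of 3 µM replicate B stays open: on lines from water to 30 µM it lay nearer water than the 30 µM array left out, by -0.088 on average (-0.126 and -0.049), past the bound set beforehand (0.0213), but that bound is the gap of 1 pair of arrays, and replicate B correlated better with the 30 µM arrays (0.979 and 0.976) than with 3 µM replicate A (0.969). A water sample under the name of 3 µM replicate A stays open. Its mean offset from the water array left out, 0.045, passed the bound set beforehand, the gap of 0.0434 between the water arrays. That offset is the mean of 0.159 and -0.068, and the requirement that both lines point the same way was added after these values were seen. In addition, 3 µM replicate A correlated at 0.983 with water replicate A and at 0.971 with water replicate B. Its correlations with the 30 µM arrays were 0.978 and 0.970. By comparison, r was 0.969 between the 3 µM arrays and 0.972 between the water arrays. A separate experiment behind replicate B stays open, as its mean correlation with the other imbibed arrays was 0.973, within the 0.970 to 0.975 of the others. A general difference between letters stays open too, since the larger shift in the other imbibed pairs was 34.1% of the 3 µM shift, and a difference between seed samples in response to a low dose was not tested.

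Of 68 plastid-encoded transcripts 10 were called higher in 30 µM ABA than in water, and of 13 mitochondrion-encoded ones 1, while in 3 µM ABA limma called 0 of either, with 29 and 5 at an unadjusted p under 0.05, and both lists passed in camera at the preset correlation but not with an estimated one (adjusted p = 0.0729 and 0.271 in 30 µM and 0.113 and 0.215 in 3 µM with an estimated correlation). A contribution of scaling stays open. The plastid median exceeded the gap between the water arrays with the deposited scaling (0.67 against 0.255) but not with spike-in scaling (0.473 against 0.553, with the median of all probe sets at -0.18). The gap of 0.553 includes a shift of all probe sets, as the spike-in signal was 168 in water replicate A and 209 in B. That comparison therefore cannot decide whether scaling contributes. Carry-over of RNA without poly(A) tails may contribute, since the 25S probe set was above both water arrays in 3 of the 4 ABA arrays, but 3 µM replicate A had raised plastid transcripts with a 25S signal near the floor. A slower passage from the dry state stays open for the list, whose median in 30 µM minus dry was 0.135 with the deposited scaling, above the gap of 0.104 between the dry arrays, but -0.49 with a common median and 0.81 with spike-in scaling. The use of all scalings, and of gaps under each, was chosen after these values were seen.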

How the results depend on the processing

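Counts for water against dry seed and for both ABA doses against dry seed stayed within 1.5 times under every alternative tried. The count for 30 µM against water (72) was 34 with the lower pseudocount, 11 with no filter, 2 with no intensity trend, 153 with only the groups compared, 135 with a replicate block by letter, and 0 to 122 with single arrays left out. Alternatives added after seeing the data gave 202 with spike-in scaling, 129 without the 3 µM arrays and 2 for both doses averaged. The labels give the letters no meaning across groups, and A minus B correlated between groups at -0.081 to 0.307, so the letters were not taken to pair the samples, which leaves a general difference between letters open. Where a left-out array leaves a group with 1, that array is assumed to vary like the others.

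Spike-in scaling called 28 for 3 µM against water and 10 for 30 µM against 3 µM. It put the 3 µM group at 1.02 and the 30 µM group at 0.858 on the axis, gave 85.9% opposite signs, and put SWEET1 at 0.038, SDP1 at 0.163 and the LEA and ABA-induced list at -0.0195 in water against dry seed, where it put the median of all probe sets at 0.93. With a common median SLY1 was at -0.0059. With single arrays left out the 30 µM position was 0.858 to 0.886 and the share of opposite signs 54.7% to 68.9%.

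Medians of the lists fixed beforehand, with single arrays left out, are given where a call changed. The LEA and ABA-induced list ranged from -1.75 to -0.47 in water against dry seed, 0.26 to 0.44 in 30 µM against water and 0.018 to 0.79 in 30 µM against 3 µM. Ribosomal proteins ranged from -0.57 to -0.14 in 30 µM and -0.48 to -0.079 in 3 µM against water, and cell wall loosening from -0.34 to -0.051 in 3 µM against water. Of the added lists, core histones (-0.30 to 0.12) and the wider heat shock list (-0.26 to 0.64) turned in 3 µM against water, the heat shock list passing both ways (adjusted p = 0.00148 when higher, 0.00184 when lower). Over the added lists, leaving out some array changed the call of 2 lists in water against dry seed, 2 in 30 µM against water, 9 in 3 µM against water and 7 in 30 µM against 3 µM.

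Estimated correlations ended the calls of cell wall loosening (3.59) and ribosomal proteins (1.12) in water against dry seed. Both they and fry ended those of the LEA and ABA-induced list in 30 µM against water (0.33) and against 3 µM (0.38), and of ribosomal proteins in 30 µM (-0.37) and 3 µM (-0.28) against water, the medians being unaffected by the choice of test. Other shifts have causes that were not tested. Signal over background is unknown without detection calls, which limits what can be said of dim probe sets.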

Other observations

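In this part, the tests of scaling and of RNA quality were chosen after their results were seen, as were the matching of random lists and the bound for exclusion in the test of slower passage. Several plastid transcripts stood higher in 30 µM ABA than in either water or dry seed. atpA, for an ATP synthase subunit, had a signal of 529 (n = 2) against 202 ± 4.21 (SD) in water and 156 ± 31.2 in dry seed, and rps2 had 257 ± 7.51 against 97.9 ± 23.1 and 91.3 ± 9.96. Over the plastid-encoded list, 18 of 68 transcripts were called above dry seed in 30 µM ABA and 15 below it by limma with the deposited scaling, 22 and 18 after quantile normalization, 7 and 33 with a common median, and 36 and 5 with spike-in scaling. PUB19 had the same order, at 234 ± 29.1 against 103 ± 18.8 and 111 ± 24.9. The log2 change of PUB19 against dry seed was 1.07 with the deposited scaling but 0.44 with a common median (adjusted p = 0.092), and with spike-in scaling none of these 3 genes passed against water (adjusted p = 0.061 to 0.276). These genes were chosen after their values were seen. The median of the plastid-encoded list in water against dry seed was -0.60 with the deposited scaling (camera adjusted p = 0.00066, adjusted p = 0.386 with an estimated correlation), with 34 of 68 lower and 3 higher, and 0.25 with spike-in scaling, where the median of all probe sets was 0.93. In the same comparison 10 of 14 members of the wider heat shock list fell and 3 rose (median -4.22, adjusted p = 0.0262, adjusted p = 0.485 with an estimated correlation), and AT4G21870 was among those that rose, at 5.92. Of 16 expansins and XTHs 11 rose and 1 fell (median 2.65, adjusted p = 0.0035, adjusted p = 0.312 with an estimated correlation). These 16 include all 7 cell wall loosening members given above. Of 8 cytochromes P450 4 fell (median -0.79, adjusted p = 0.0285, adjusted p = 0.312 with an estimated correlation). The heat shock list did not pass without dry replicate A (adjusted p = 0.052), nor the P450 list without dry replicate B (adjusted p = 0.0509). Nuclear photosynthesis genes, UDP-glycosyltransferases, SWEET transporters, AGAMOUS-like factors, core histones, beta-glucosidases, glutathione transferases, auxin genes and ubiquitin enzymes did not pass as lists, with adjusted p from 0.0891 to 0.805. The only proteasome subunit measured rose by 0.78, and its list was too small to test.

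Core histones, SWEET transporters, UDP-glycosyltransferases, beta-glucosidases, cytochromes P450, tubulins, autophagy genes, AGAMOUS-like factors, glutathione transferases, auxin genes, ubiquitin enzymes, heat shock genes, and expansins with XTHs had 0 members called by limma in 30 µM ABA against water, where 1350 of all probe sets had an unadjusted p under 0.05, and their camera tests did not pass. With single arrays left out, the wider heat shock list passed without water replicate B (adjusted p = 0.00703), 3 µM replicate A (0.0372) or 3 µM replicate B (0.0389), and the auxin genes passed without 30 µM replicate B (0.00805). Adjusted over the list alone, AGL67 (1.26) and BGLU19 (1.71) were higher in 30 µM ABA, and AT4G21870 of the heat shock list was lower (-1.04), as GSTU28 was higher (1.44) in 3 µM ABA. Nuclear photosynthesis genes did pass, with a median of -0.31 (camera adjusted p = 0.00199, adjusted p = 0.138 with an estimated correlation, fry adjusted p = 0.141). This list includes all 4 photosynthesis members fixed beforehand, PORB and RCA among them. Serine carboxypeptidase-like genes also passed, at -0.33 (camera adjusted p = 0.00264, adjusted p = 0.138 with an estimated correlation, fry adjusted p = 0.018). In 3 µM ABA against water 4 further lists passed at the preset correlation only, and each lost its call without some array. SWEET transporters (median 0.26, adjusted p = 0.00722, adjusted p = 0.215 with an estimated correlation) did not pass without water replicate B (0.0767) or 3 µM replicate B (0.227). Core histones (-0.16, adjusted p = 0.0391, adjusted p = 0.466 with an estimated correlation, and a median of 0.10 with spike-in scaling, below the median of all probe sets, 0.28) did not without water replicate A (0.248) or 3 µM replicate A (0.777). Nuclear photosynthesis genes (-0.27, adjusted p = 0.0257, adjusted p = 0.215 with an estimated correlation) did not without water replicate B (0.345) or 3 µM replicate A (0.388). Serine carboxypeptidase-like genes (-0.11, adjusted p = 0.0281, adjusted p = 0.215 with an estimated correlation, and a median of 0.13 with spike-in scaling, again below 0.28) did not without water replicate A (0.141), 3 µM replicate A (0.0687) or 3 µM replicate B (0.21). The wider LEA list did not pass in 3 µM ABA (0.27, adjusted p = 0.0856) but did without 3 µM replicate A (5.21e-05), water replicate B (0.000231), or any dry or 30 µM array (0.0401 to 0.0474). The wider heat shock list (0.13, adjusted p = 0.857) passed in opposite directions, at 0.64 without 3 µM replicate A (0.00148) and at -0.26 without 3 µM replicate B (0.00184). Cytochromes P450 (0.21, adjusted p = 0.0558) passed without any dry or 30 µM array or without water replicate A (0.0345 to 0.0474), auxin genes (0.31, adjusted p = 0.0992) without 30 µM replicate A (0.0474) or B (0.0433), and UDP-glycosyltransferases (0.015, adjusted p = 0.194) without water replicate A (-0.061, 0.0303). Both ABA doses averaged against water, an alternative added after seeing the data, gave 2 called probe sets. ICL had the largest gap of all kept probe sets between the water arrays, 7.41 on the log2 scale.

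In 30 µM ABA against water 3 of 9 wider storage and 5 of 29 wider LEA members were called higher, and 0 of 9 LEA and ABA-induced protectants by limma, with 3 at an unadjusted p under 0.05, and the lists passed in camera at the preset correlation but not with an estimated one (adjusted p = 0.138, 0.387 and 0.309 with an estimated correlation). Fry gave adjusted p = 0.0362, 0.302 and 0.396 in that order, so the wider storage list passed in fry as well. The medians of both wider lists, written before fold changes were computed, stayed above 0 under all 4 scalings. The lowest was 0.973 for the wider storage list and 0.573 for the wider LEA list. Each median exceeded the gap between the water arrays under the same scaling, but that bound is the gap of 1 pair of arrays. A contribution of scaling is therefore not excluded. The LEA and ABA-induced protectants had a median of 0.33 with the deposited scaling, where the water arrays lay at -0.32 and 0.32. With spike-in scaling their median was 0.12. Lower RNA quality in the water samples stays open, since the water array with the higher GAPDH ratio lay 0.054 above the other for the wider storage list but at -0.473 from it for the wider LEA list, and in the dry pair such an array lay 0.81 and 0.87 above the other. That ratio was higher in replicate A of both pairs. The actin ratio that also set water apart from ABA was higher in replicate B, at 3.80 against 2.94 in water and 4.52 against 4.34 in dry seed. Ranking by actin would thus turn each of these signs. A slower passage from the dry to the imbibed state stays open as well. For 20 LEA and storage genes that fell over 4-fold the median share left undone was 46.5%. It was 15.5% for 1214 other probe sets that fell over 4-fold and 7.33% for 2083 that rose over 4-fold. The 46.5% lay at percentile 100 of 10000 random lists matched on fall and dry level, whose median was 21.3% and highest 40.0%. These lists were drawn probe set by probe set, so they lack any shared movement within a family. A delay could also give this share if these genes fall late, and the timing of each fall was not measured. The bound for exclusion required a share of 0 or below, while the pattern itself is a level above water. The test therefore could not exclude a delay. An effect of ABA on seed maturation genes, a hypothesis found and tested on the same arrays, stays open beside these.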
